A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

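Saccharomyces cerevisiae cells of a hog1 mutant were studied, altered in the gene of Hog1, the mitogen-activated protein kinase (MAPK) of the high-osmolarity pathway. Per the labels, the cells grew in the rich medium YEPD at 24 °C, each culture was divided, and 1 part received Zymolyase 100T at 5 units/ml while the other grew on without it; RNA was taken at 3 h. Zymolyase is an enzyme preparation with beta-1,3-glucanase activity that digests the yeast cell wall. Total RNA of 2 cultures was reverse transcribed with Cy3 or Cy5 nucleotides and hybridised to 2-colour arrays, with 2 hybridisations per culture that included a dye swap, which gave 4 arrays. The treated RNA carried Cy3 on arrays 1 and 3 and Cy5 on arrays 2 and 4. The labels do not say which arrays shared a culture, and no array of wild-type cells was analysed here.

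The authors deposited 1 table with a normalized log2 ratio per array row and array, and no spot intensities were used here. Image analysis, background correction, normalization, the filter that left rows blank, and the condition in the numerator are not given in the sources used here. The deposited column medians were −0.06, 0.02, −0.08 and −0.03 for arrays 1 to 4, which was kept as deposited. The base was settled from the values: after the sign of arrays 2 and 4 was turned, all 9281 values that stood for a ratio under 1 were base-2 logarithms of a linear ratio with 4 decimals, to the precision of the deposited digits, where 56.5% would be by chance. For the inverse ratio the share was 55.4%, against 54.9% by chance, so the linear ratios had the same condition as numerator on all 4 arrays. As deposited, arrays of opposite dye orientation correlated across genes with Pearson r of −0.56, −0.52, −0.17 and −0.31, and arrays of the same orientation with 0.55 and 0.64, and by Spearman with −0.13, −0.16, 0.06 and −0.11, against 0.36 and 0.42, so the deposited sign followed the dye. By rank, arrays of the same orientation agreed better with each other than with arrays of the opposite orientation. Over tested genes, the scaled median absolute deviation was 0.23 for the mean ratio and 0.21 for the mean with signs turned by dye. Small ratios from arrays of 1 orientation can therefore reflect the dye. The signs of arrays 2 and 4 were turned, and the ratio is read as treated over untreated. This direction is likely and not stated: it rests on the shared numerator of the linear ratios, on the treated against untreated design, and on the genes PRM1, FIG1 and PGU1, which are nearly silent in unstimulated cells and are far above 0 in this reading. The pheromone list, which holds these 3 genes, therefore gives no independent evidence of direction. With the opposite numerator every sign would turn and the counts of higher and lower would swap, while sizes, p-values and total counts would stand.

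The table held 6209 rows, of which 2 were controls (3XSSC and Arabidopsis) and were left out. Of the 6207 yeast rows, 5654 matched a locus tag in NCBI RefSeq's gene table of assembly R64 and took their symbol from it, and the other 553 kept the name in the table. Each gene had 1 row. Coordinates are not printed, because the sources used here name no genome build. Values were present for 45.0%, 67.1%, 85.7% and 82.6% of the yeast rows on arrays 1 to 4. The 2715 rows with a value on all 4 arrays were tested, and 98 of these had no matching locus tag. The number of arrays limits the precision. Amplicons of gene families and overlapping genes can share labelled cDNA.

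Cultures were the replicates (n = 2). For each of the 2 ways in which the 4 arrays can form dye-swap pairs (arrays 1+2 and 3+4, or arrays 1+4 and 3+2), the log2 ratios of a pair were averaged and the 2 means tested against 0 with limma 3.58.1 (lmFit and eBayes, R 4.3.3). The larger of the 2 p-values was kept for each gene and adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. The prior degrees of freedom of the variance model were 4.12 for the first pairing, and infinite for the second. A count without a test was set beside it: genes with a mean log2 ratio of at least 1 in size and the same sign on all 4 arrays, against the same count after the signs of 2 of the 4 arrays were turned. Errors are the SD over 4 arrays unless another is named. An exact sign-turn test of 4 arrays cannot go below p = 0.125, so it was not used to call genes.

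The 21 gene lists were tested with limma's camera on the same culture means with an inter-gene correlation preset at 0.01, the larger p of the pairings kept and adjusted over the 21 lists; an estimated correlation was the alternative. Of the 21 lists, 1 is not reported here. Named genes followed a rule fixed before the data were examined, together with the tests, lists and most alternatives: the 10 largest rises and falls among called genes (filled with genes of 1 sign on all arrays that did not pass), up to 3 members per list with the largest mean ratio in size, and HOG1, SLT2, RLM1, KDX1, CRH1, PIR3, NCW2, PRM5, CWP1, GSC2, GPD1, STL1, HSP12 and CTT1. Other genes are said to be chosen after their values were seen. Of the lists, the members by rule are given in part.

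The gene test was tested on 10 simulated data sets of 2715 genes for this comparison. It recovered 10.6% of genes with a 1.41-fold change, 85.6% with a 2-fold change, 98.8% with a 4-fold change and 99.6% with an 8-fold change, and 7.5% of its 1593 calls were false, above the nominal 5% (adjusted p threshold 0.05). Of 20 simulated lists shifted by 0.5 on the log2 scale, 20 were called, and of 400 unshifted lists 0 were. Variances of the simulated genes came from the variance model that limma fitted to these arrays, so the rates hold only as far as that model does. Simulated genes were drawn independently of each other, with arrays 1+2 and 3+4 as the cultures. The simulated lists therefore do not show how often lists of co-regulated genes are called falsely. Alternatives covered the pairing, arrays as replicates, the variance model, centring, scale, missing values, dye orientation, single arrays left out and the size threshold. In a fit without 1 array, the array left without its pair stood alone as a culture mean, so its dye effect was not cancelled. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the remaining steps, and statmod 1.5.0 in R.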

Results

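The response of hog1 cells to Zymolyase was measured on 4 arrays from 2 cultures, each array comparing the treated with the untreated part of a culture at 3 h. Arrays 1 to 4 gave values for 2794, 4162, 5322 and 5127 yeast rows, and 2715 genes had a value on all 4. The comparison asked which transcripts change in hog1 cells when the cell wall is digested. HOG1 itself had no value on any of the 4 arrays, so it gives no check of the strain. Ratios are treated over untreated, a direction that is likely but not stated in the sources used here; the opposite numerator would turn every sign and swap the counts of higher and lower, while sizes, p-values and total counts would stand.

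Genes of mating, and PGU1 of filamentous growth, rose most in the treated cells. PRM1, which acts in plasma membrane fusion during mating, had a mean log2 ratio of 6.51 ± 3.01 (SD, n = 4 arrays), 91.0-fold, with adjusted p = 0.00276 by limma. FIG1, a membrane protein made in response to mating pheromone, rose 42.4-fold (5.40 ± 0.88, adjusted p = 0.000698), and PGU1, a polygalacturonase made during filamentous growth, 41.6-fold (5.38 ± 0.72, adjusted p = 0.000698). PRM3, which acts in nuclear fusion, rose 33.1-fold, AGA1, the anchor subunit of a-agglutinin, 31.8-fold and PRM6 25.9-fold. The size for PRM1 was poorly fixed, with 4.15 and 4.29 on arrays 1 and 3 against 10.55 and 7.03 on arrays 2 and 4. It was not called with a robust variance model (adjusted p = 0.0763 by limma) or with the scale made equal between arrays (adjusted p = 0.0504). The other genes among the 10 largest rises were YIL082W, a row of the Ty3 retrotransposon (13.6-fold), NFG1, also known as YLR042C (11.4-fold), ASG7 (9.52-fold) and PRM5, which is induced by cell wall stress (log2 ratio 3.17 ± 0.78).

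In all, 60 of 2715 genes were called, 55 higher and 5 lower, each with the same sign on all 4 arrays. The median log2 ratio of the 55 was 1.52, and 47 of them were past 2-fold, 17 past 4-fold and 12 past 8-fold. At an unadjusted p under 0.05 there were 400 genes, of which 221 were higher. By size alone, 60 genes were past 2-fold with 1 sign on all arrays (54 higher, 6 lower), and 52 of these were also called. After the signs were turned by dye, 5 genes met this size rule, and after the signs of arrays 3 and 4, or of arrays 2 and 3, were turned, 2 and 0 did. The count of called genes fell to 22, with 0 lower, without array 2 (21 of the 22 shared with the 60), and rose to 129 without array 3, of which 100 were higher and which included all 60. In fits without 1 array, 1 of the 2 culture means was a single array, so its dye effect did not cancel. If arrays 1 and 4, and 3 and 2, were the pairs, 277 genes were called (202 higher and 75 lower), and pairs 1+2 and 3+4 gave the 60.

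**Figure D1:**
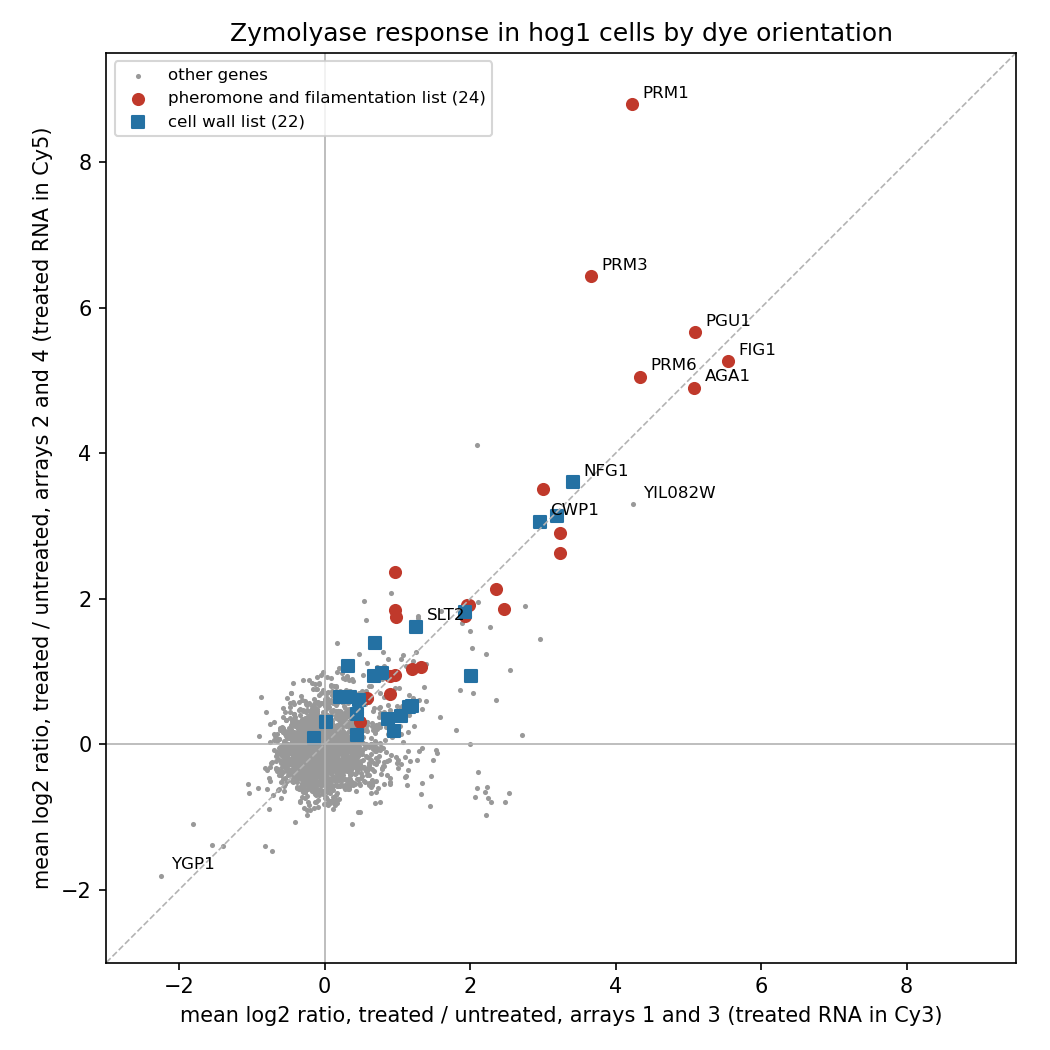
Mean log2 ratio (treated over untreated) of arrays 1 and 3, with treated RNA in Cy3, on the x axis against that of arrays 2 and 4, with treated RNA in Cy5, on the y axis; each point is 1 of 2715 genes, red circles are the 24 tested members of the pheromone and filamentation list, blue squares the 22 of the cell wall list, and the dashed line marks equal values. PRM1 lies at 4.22 and 8.79 and PRM3 at 3.66 and 6.43, above the line.

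All 24 tested members of the pheromone and filamentation list, genes under the transcription factors Ste12 and Tec1, had a mean above 0, and 20 rose and 0 fell. Adjusted over the list alone, 24 rose. Beside the genes above, these included AGA2, the adhesion subunit of a-agglutinin (8.39-fold), and BAR1, a protease that degrades alpha-factor (3.82-fold). The MAPKs FUS3 and KSS1 of the mating and filamentation pathways rose 3.87-fold and 4.75-fold, and STE2, the alpha-factor receptor, 2.28-fold; AGA2, BAR1, FUS3, KSS1 and STE2 were chosen after their values were seen. The members that did not pass were FAR1 (0.80 ± 0.17), TEC1 (0.92 ± 0.21), GPA1 (0.61 ± 0.12) and MFA2 (0.40 ± 0.21), also named after their values were seen. FLO11, a further member of the list, had no value on any array. The list's median log2 ratio was 1.94, and camera gave an adjusted p of 1.76e-40. It was not called with an estimated correlation (camera p = 0.0676 before adjustment, adjusted p = 0.77). That setting rests on 1 residual degree of freedom and called 0 of the 21 lists. Histones and iron, which were not called in the 4-array fit, had the same adjusted p of 0.77 there. The preset setting used the same 2 culture means and took the genes of a list as nearly independent, with a correlation of 0.01. Its small p-values, for this and the other called lists, are therefore not a measure of the spread between cultures. Another list test of limma, fry, gave the pheromone list an adjusted p of 0.255.

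Of the Slt2/Rlm1 cell wall list, genes of the cell wall integrity MAPK pathway and of wall remodelling, 22 of 37 members were tested. Of these, 7 rose and 0 fell. Adjusted over the list alone, 18 rose. SLT2, the MAPK of this pathway, rose 2.71-fold (1.44 ± 0.25, adjusted p = 0.00869), and CRH1, which links chitin to glucan, 1.85-fold (0.88 ± 0.18, adjusted p = 0.0461). NFG1 and PRM5 were the largest rises of the list, and GFA1, at the entry to chitin precursor synthesis, rose 3.67-fold, SED1 2.77-fold and TIP1 2.05-fold (these 3 chosen after their values were seen). Whether NFG1, PRM5 or other members rose under Slt2 and Rlm1 or with the mating genes was not tested. CWP1, a wall mannoprotein, had a mean of 3.01 ± 1.43 and did not pass (adjusted p = 0.0824), with 4.47 and 3.94 on arrays 1 and 2 against 1.44 and 2.18 on arrays 3 and 4. PIR3 (0.72 ± 0.41), NCW2 (0.81 ± 0.29) and GSC2 (0.61 ± 0.63), a glucan synthase subunit, did not pass either. RLM1, the transcription factor under Slt2, had values of 1.13 and 0.85 on arrays 3 and 4, and KDX1, a kinase-like gene of the same pathway, −0.13 on array 3. The list's median was 0.77, 21 of the 22 means lay above 0, and camera gave an adjusted p of 1.67e-18. With an estimated correlation camera gave p = 0.107 before adjustment and an adjusted p of 0.77. Without array 2, in a fit where 1 culture mean was a single array with its dye effect not cancelled, none of the list's 7 calls was kept. NFG1, PRM5, SLT2 and CRH1 had mean log2 ratios of 3.49, 3.14, 1.32 and 0.80 there and adjusted p of 0.0597, 0.0854, 0.0854 and 0.248 by limma, and GFA1, SED1 and TIP1 adjusted p of 0.0668, 0.117 and 0.322.

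**Figure D2:**
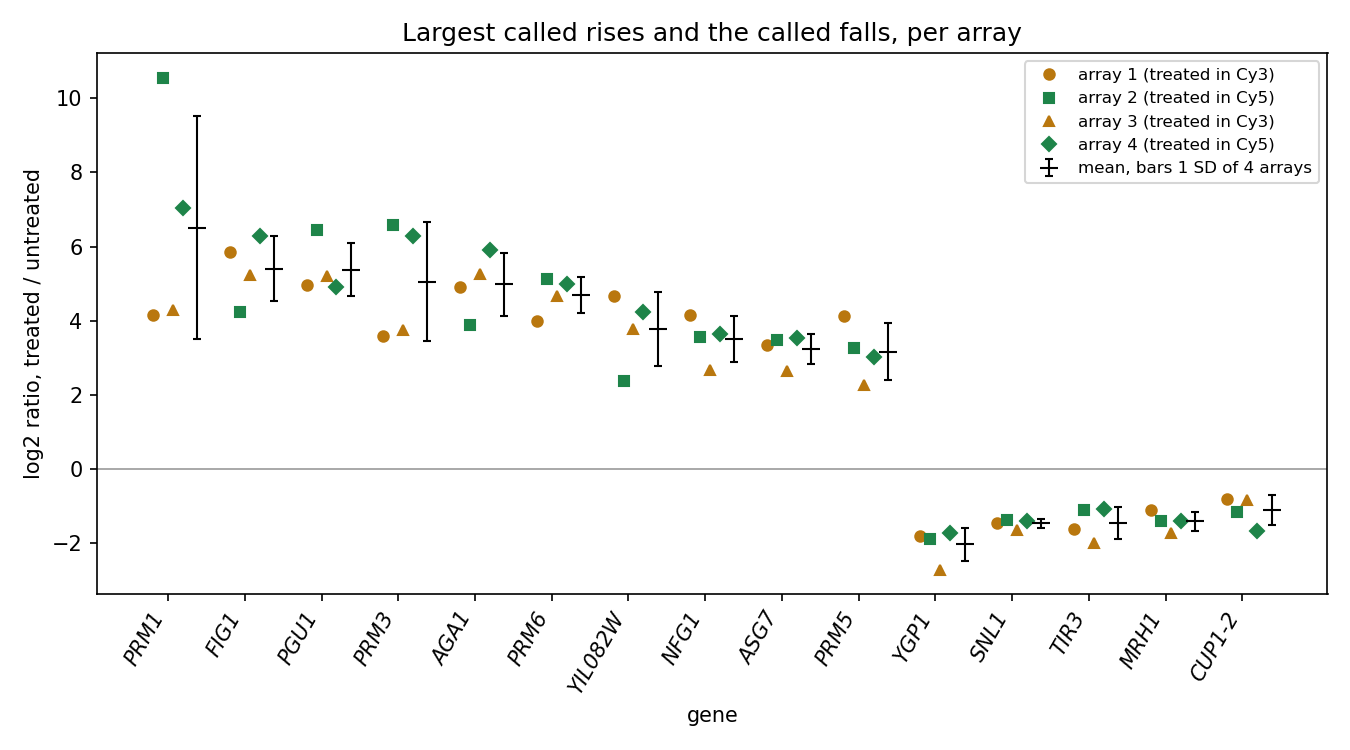
Log2 ratio (treated over untreated) on each of the 4 arrays for the 10 largest called rises and the 5 called falls, with symbols for the arrays, colours for the dye of the treated RNA, and the mean with bars of 1 SD over 4 arrays. PRM1 ranges from 4.15 to 10.55, and the 5 falls lie between −2.70 and −0.80.

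The 5 called falls were YGP1, a secreted glycoprotein, with a mean log2 ratio of −2.03 ± 0.46 (adjusted p = 0.00485), SNL1 (−1.46 ± 0.12, adjusted p = 0.0085), TIR3, a wall mannoprotein (−1.45 ± 0.44, adjusted p = 0.00891), MRH1 (−1.40 ± 0.25, adjusted p = 0.0127) and CUP1-2, a copper metallothionein (−1.11 ± 0.40, adjusted p = 0.0285). CUP1-1, the other copy of this gene, had −1.03, 0.0424 and −0.99 on arrays 2, 3 and 4 and was not tested (chosen after its values were seen), while CUP1-2 had −0.83 on array 3. None of the 5 was called without array 2, where the means were −2.08, −1.49, −1.56, −1.40 and −1.10 and the adjusted p-values 0.0888, 0.0668, 0.1, 0.1 and 0.205. Of the genes next in size that did not pass, GPX2 had −1.09 ± 0.53 and URA1, of pyrimidine synthesis, −0.83 ± 0.22 (adjusted p = 0.0524 for each). NCE102 (−0.85 ± 0.39), MDH2 (−0.80 ± 0.35) and PDR16 (−0.76 ± 0.24) did not pass either.

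Of the osmostress list of genes that depend on Hog1, 10 of 23 members were tested, so its values do not speak for the whole list. It had 0 called members, 6 means above 0 and 4 below, a median of 0.05 and an adjusted p of 0.99. Its members with the largest mean ratios in size were GRE2 (−0.57 ± 0.32), GRE3 (0.45 ± 0.33) and GPP2 (−0.41 ± 0.20), and GPD1, of glycerol synthesis, had 0.38 ± 0.61. The list's mean log2 ratio of −0.04 turned to 0.12 with rows of each dye orientation (adjusted p = 0.513). STL1, a further member of the osmostress list, had no value on any array. Of 8 members with values on 1 to 3 arrays, which were not tested, 3 had all values above 0, 2 all below 0 and 3 both signs. Among them were ALD3 (0.81 and 1.24) and SIP18 (1.19 and 0.72) on arrays 3 and 4, and ALD2 (−0.08, −0.32 and −0.32) on arrays 2, 3 and 4, chosen after their values were seen. Of the 34 general stress genes 15 were tested. Among these, DDR48 rose 3.84-fold (1.94 ± 0.44, adjusted p = 0.0035) and YGP1 fell, the list's median was 0.41 and its adjusted p 0.0571. Adjusted over the list alone, 7 were higher and 1 lower. With arrays 1+2 and 3+4 as pairs the list's adjusted p was 0.000117, against an adjusted p = 0.77 with an estimated correlation. HSP12, of the general stress list, had −0.58 and −0.46 on arrays 3 and 4, and CTT1, of the same list, had no value on any array. DDR48 overlaps YMR173W-A, which was also called (1.73 ± 0.75), so their signals cannot be separated here.

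Ribosomal lists were slightly lower. Of 127 tested ribosomal protein genes 0 were called, 116 had a mean below 0, the median was −0.14 and the adjusted p 0.0299, against an adjusted p = 0.77 with an estimated correlation. The list was not called without array 3 (adjusted p = 0.155), and centring each array moved its mean log2 ratio from −0.1401 to −0.0924 (adjusted p = 0.00112). RPS29B (−0.44 ± 0.40) and RPL36A (−0.43 ± 0.32) were the lowest and did not pass. Of 33 tested ribosome biogenesis genes 0 were called, 32 had a mean below 0, the median was −0.27 and the adjusted p 0.00854, against an adjusted p = 0.77 with an estimated correlation. It was not called on the Cy3-treated arrays alone (mean −0.1286, adjusted p = 0.134), against a mean of −0.402 on the Cy5-treated arrays. RRS1 had −0.58 ± 0.38.

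None of the other 14 lists reported here was called in the 4-array fit, each with 0 called members. Their medians and adjusted p-values by camera were 0.13 and 0.442 for heat shock chaperones, 0.29 and 0.242 for the unfolded protein response, 0.09 and 0.533 for calcineurin, 0.15 and 0.285 for glycolysis and fermentation, and −0.16 and 0.222 for respiration. Amino acid biosynthesis had 0.07 and 0.665, sulfur assimilation 0.28 and 0.222, oxidative stress −0.22 and 0.242, the proteasome 0.01 and 0.99, and G1/S genes −0.00 and 0.918. Histones had −0.25 and 0.222, phosphate −0.15 and 0.222, iron −0.09 and 0.242, and ergosterol −0.11 and 0.497. Tested members were only 3 of 12 for calcineurin, 9 of 23 for sulfur assimilation, 15 of 26 for iron and 16 of 26 for G1/S. These values therefore do not speak for the whole of such lists. Larger member values that did not pass over all tested genes were KGD1 at 0.77 ± 0.39, MET6 at 0.77 ± 0.43 and QCR6 at −0.74 ± 0.41. Adjusted over the list alone, 1 respiration gene was higher and 2 were lower. By the same measure 1 sulfur assimilation and 1 calcineurin gene were higher, 1 oxidative stress gene was lower, and the other lists of this paragraph had 0. Lists that were not called passed under some of 16 alternatives: general stress under 11, sulfur assimilation under 8, glycolysis and histones under 7 each, heat shock under 4, and the unfolded protein response, phosphate and respiration under 3 each. Their lowest adjusted p-values were, in that order, 0.000117, 0.00463, 0.0167, 0.0144, 0.0164, 0.0181, 0.0338 and 0.0401.

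**Figure D3:**
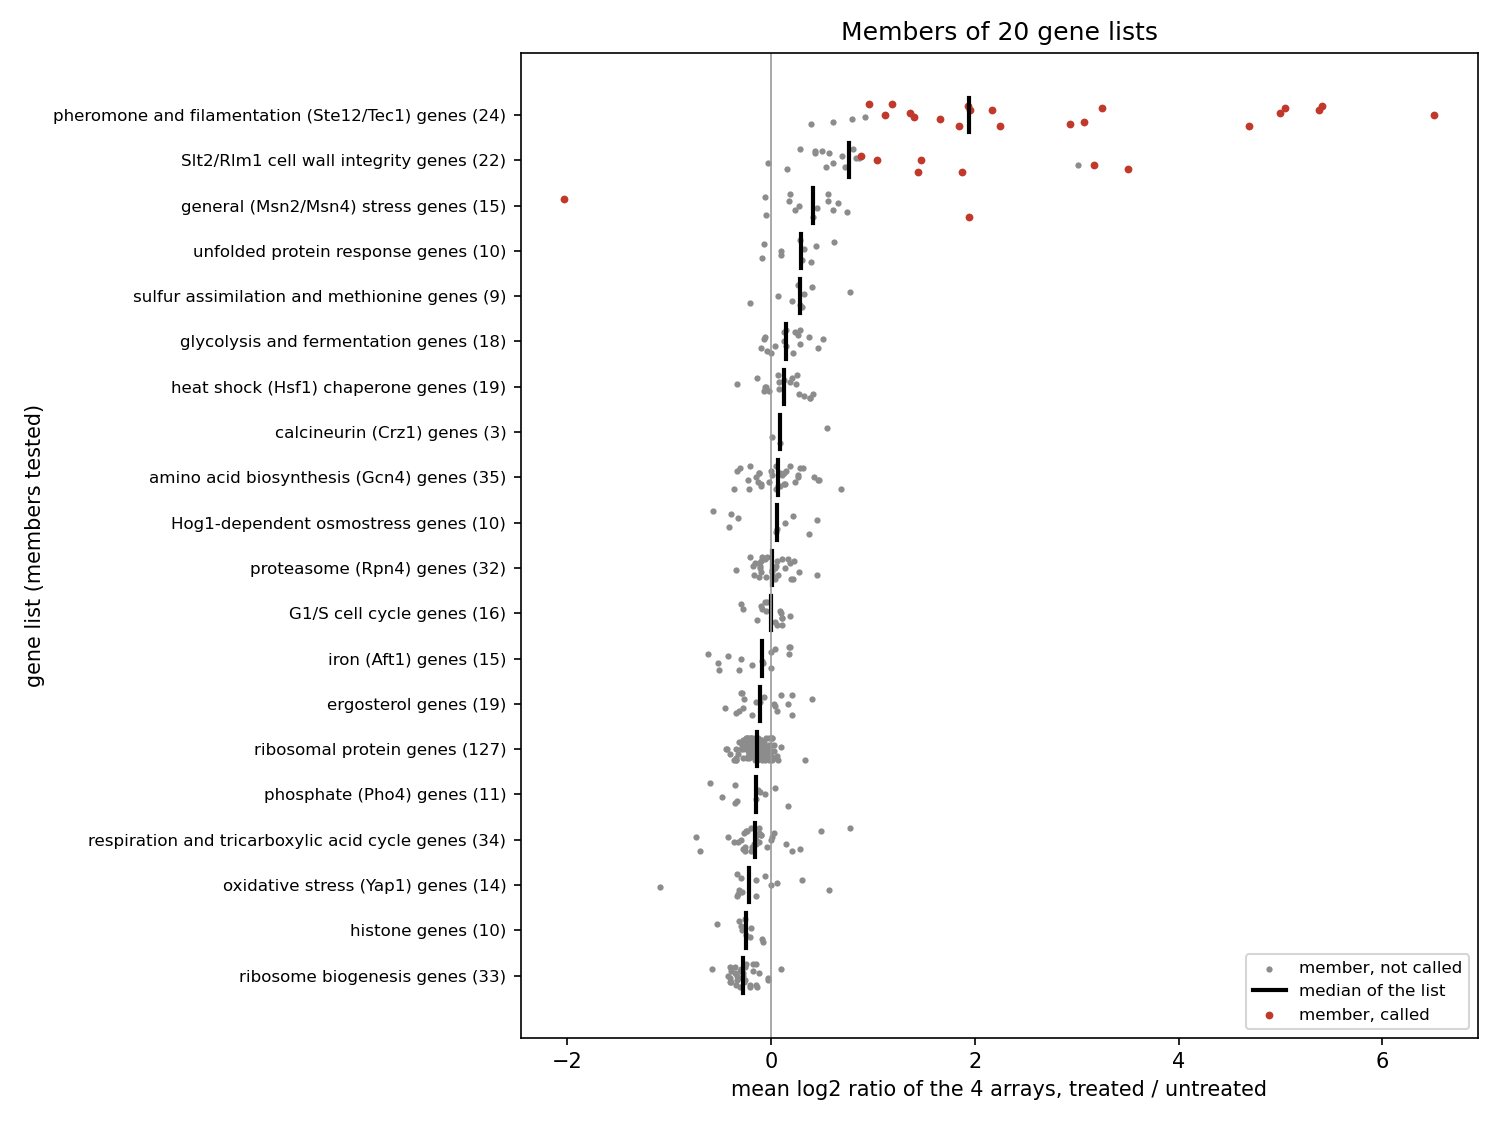
Mean log2 ratio over 4 arrays (treated over untreated, x axis) of the tested members of each of 20 gene lists (y axis, with the number tested), with called members in red, others in grey and the list's median as a black bar. The pheromone list, with a median of 1.94, and the cell wall list, with 0.77, lie furthest above 0, and ribosome biogenesis, at −0.27, lowest.

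Cultures were the replicates (n = 2), and the arrays that shared a culture are not known, so p-values rest on the larger of 2 pairings. No wild-type cells were analysed here, and the values do not show which changes depend on the hog1 mutation.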

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

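The tests of the dye, array and culture explanations below, of the retrotransposon rows and of the orientation gap were chosen after the results were seen. Of 82 named genes with a value on all arrays, 4 had 1 array far from the other 3, where chance gives about 4.1. YGP1 was −2.70 on array 3 against −1.88 to −1.72 on the others. PDC6, a pyruvate decarboxylase gene, was 2.02 on array 3 against −0.19 to 0.18, and TRP5 1.32 on array 3 against 0.10 to 0.31. ARG4 was −0.0504 on array 2 against 0.83 to 1.00. Of the 4, 3 lay on array 3.

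The count of 60 genes past 2-fold was weighed against dye bias and against differences between arrays or cultures. Turning the signs by dye left 5 genes past 2-fold, which argues against dye bias as the cause of the count. Turning the signs of 2 arrays across the dyes left at most 2, which argues against differences between arrays or cultures alone. No other treatment was measured, so whether the response is specific to wall digestion stays open.

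Array 3 stood apart in a further way: 29 tested rows exceeded every other array by over 1.5 on the log2 scale there, against 0, 1 and 0 on arrays 1, 2 and 4. Of these, 8 belong to 1 family of 31 unnamed genes that share an annotated length of 1323 bases in R64, the gag reading frames of the Ty1 retrotransposon, with a median of 4.05 on array 3. A difference between the 2 cultures as the whole cause would have been seen on array 2 or 4, of which 1 shares that culture, but the medians of all 8 tested members of the family there were −1.31 and 0.0308. Dye orientation as the whole cause would have been seen on array 1, where the median was 0.34, but a dye effect as part stays open, since all 5 genes past 2-fold after the turn by dye are among the 29 and −1.31 has the sign of such an effect. None of the 8 rows was called, and a fault or event on array 3 alone stays open; HAC1, at 4.52 on array 3 and at most −0.09 on the others, and PDC5 are in the same set.

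PRM1, PRM3 and ZPS1 had ratios larger where the treated RNA carried Cy5, by 4.57, 2.77 and 2.03 on the log2 scale. An untreated signal near background could inflate such gaps in genes with large ratios. Other called genes had gaps of the opposite sign, the largest −1.33 for YFL-TYB and −1.07 for SED1. FIG1 and AGA1, with mean log2 ratios of 5.40 and 4.99, had gaps of −0.28 and −0.18. Across the 60 called genes, which are not independent replicates, the size of the gap correlated with the size of the ratio at Spearman rho = 0.159 (permutation p = 0.22) and Pearson r = 0.462 (permutation p = 0.0011), with r = 0.279 when the 2 genes farthest from the median ratio were left out. Spot intensities were not used, so this explanation cannot be told apart from gene-specific dye effects.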

How the results depend on the processing

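Values limited to a log2 ratio of 2, and the arrays of 3 with all their rows, were added after the data were examined, as was the Spearman correlation; the other alternatives were fixed before. Called genes numbered 60 and stayed within 1.5 times of that, between 40 and 89, for arrays 1+2 and 3+4 as pairs, a robust variance model (68), centring on the median (89, 81 higher), equal scale between arrays (41, of which 40 were shared), rows with at least 1 array of each dye orientation (66 of 5107), the Cy5-treated arrays alone (80), limited values (40) and arrays 2, 3 and 4 with all their rows (89 of 4036). They moved to 277 for arrays 1+4 and 3+2 as pairs (72.9% higher, against 91.7%), 119 for 4 arrays with a dye term, 97 without it, 149 with the culture as a random block (79.9% higher), 141 for the Cy3-treated arrays alone, and 129 for arrays 1, 2 and 4 with all their rows (77.5% higher). Without 1 replicate array they ranged from 22 (array 2) to 129 (array 3), and 20 genes were called in every such fit and in the 4-array fit. The cause was not tested.

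Genes past 2-fold numbered 60, and 130 past 1.5-fold, 31 past 3-fold, 34 past 2-fold on each array, 92 with rows of each orientation and 105 on the Cy3-treated arrays alone. Without 1 array they ranged from 59 to 75. Called lists numbered 4, and 11 for pairs 1+2 and 3+4, 12 for 4 arrays with a dye term, 8 without it, 0 with an estimated correlation, 0 with fry, 9 after centring, 8 with rows of each orientation, 7 on the Cy3-treated arrays, 8 on the Cy5-treated arrays and 7 on arrays 2, 3 and 4. Without 1 array they ranged from 3 to 7. With an estimated correlation all 4 called lists had an adjusted p of 0.77, and fry gave 0.327 for the cell wall list, 0.255 for the pheromone list, 0.408 for ribosomal proteins and 0.33 for ribosome biogenesis; each rests on 1 residual degree of freedom. The camera fit with the preset correlation used the same 2 culture means. Ribosome biogenesis had 0.134 on the Cy3-treated arrays alone. Without 1 array the adjusted p ranged from 2.20e-67 to 4.68e-36 for the pheromone list, from 1.29e-22 to 1.56e-13 for the cell wall list, from 0.00149 to 0.0272 for ribosome biogenesis and from 0.00932 to 0.155 for ribosomal proteins. The mean correlation of arrays of opposite orientation was −0.391 by Pearson and −0.0858 by Spearman. The cause of these changes was not tested.

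With the opposite numerator the shares higher would be shares lower. Direction turned only in lists and genes that were not called in the 4-array fit. Of these, HAC1 passed below 0 on the Cy5-treated arrays (adjusted p = 0.0408), without array 3 (0.031) and on arrays 1, 2 and 4 with all their rows (0.031), and above 0 on the Cy3-treated arrays (mean 2.22, adjusted p = 0.0414) and with pairs 1+4 and 3+2 (0.00142). The adjusted p was 0.934 for the osmostress list and 0.961 for G1/S after centring, 0.513 and 0.722 with rows of each orientation, 0.749 and 0.628 on the Cy5-treated arrays, and 0.93 and 0.933 on arrays 2, 3 and 4. On the Cy5-treated arrays heat shock and calcineurin had 0.857 each, and glycolysis and the proteasome 0.837 each; the proteasome had 0.966 on arrays 2, 3 and 4. Mean log2 ratios on the Cy3-treated arrays were 0.0064 for RPA34, −0.132 for PRI1 and −0.072 for GPD1. On the Cy5-treated arrays they were −0.98 for HAC1, −0.22 for KAR2, −0.22 for PMR1, −0.44 for PDC5, −0.18 for PDC6, −0.0539 for PGI1 and 0.14 for PCL1. On arrays 1, 2 and 4 they were −0.68 for HAC1, −0.0869 for PMR1, −0.0415 for CNB1, −0.0769 for PDC5 and −0.0554 for PDC6, and HAC1 had −0.0102 with limited values. Without 1 array, the ranges were −0.68 to 1.22 for HAC1, −0.0869 to 0.204 for PMR1, −0.153 to 0.172 for CNB1, −0.0769 to 0.891 for PDC5 and −0.0554 to 0.681 for PDC6, and for the adjusted p 0.533 to 0.962 for the proteasome and 0.612 to 0.964 for G1/S.

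Of the 18 named called genes, 8 stayed called in all 18 alternatives run. SLT2 and CRH1 lost the call in 1 and 5 of them (highest adjusted p 0.0854 and 0.248). Of the named genes' values in the 14 settings that include arrays 1, 2 and 4 and arrays 2, 3 and 4 with all their rows, 997 kept direction and side, 128 passed newly, 7 lost the call and 16 turned, 5 of them on arrays 1, 2 and 4. No paired analysis was possible because there is only 1 group, in which each ratio already pairs a treated with an untreated part of a culture. The alternative of each probe alone was not run, since each gene had 1 row. Signal over background was not used here, so what low signal limits is not known.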

Other observations

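The genes in this and the next paragraph were chosen after their values were seen. CHS7, which acts in the export of chitin synthase 3 from the endoplasmic reticulum, rose 3.43-fold (1.78 ± 0.20, n = 4 arrays), its activator SKT5 1.90-fold and PGM1, a phosphoglucomutase, 1.92-fold. The wall stress sensors WSC2 and MID2 rose 2.41-fold and 1.81-fold, with SDs of 0.04 and 0.45 on the log2 scale. SVS1 rose 5.02-fold, PRY2 4.10-fold, PPR1, the activator of pyrimidine synthesis genes, 3.29-fold and SUC2, invertase, 2.16-fold. URA1 (−0.83 ± 0.22) and URA4 (−0.55 ± 0.19), of pyrimidine synthesis, did not pass. The hexose transporter genes HXT6 and HXT7 had means of 1.16 and 1.10 and did not pass, with 1.76 and 1.66 on arrays 1 and 2 for HXT6 against 0.80 and 0.41 on arrays 3 and 4. Of the 60 called genes, 31 belong to none of the lists. Of the called genes named in this and the next paragraph, CHS7, SVS1 and YIL082W kept their calls without each array in turn; the others lost theirs without array 2, where WSC2 had an adjusted p of 0.0905, MID2 0.454 and ZPS1 0.2.

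Also outside the lists, ZPS1 rose 8.59-fold, PRM9 2.38-fold, AFB1 2.20-fold, GIC2 1.86-fold and STE14, which methylates a-factor, 1.80-fold. Other genes had values on 3 arrays only and were not tested: FIG2 at 2.83, 2.96 and 6.19, AFR1 at 2.37, 2.09 and 3.46 and SAG1, alpha-agglutinin, at 1.06, 1.477 and 1.96 on arrays 1, 3 and 4, and STE12 at 0.70, 1.63 and 0.94 on arrays 2, 3 and 4. YRO2 was −1.59, −1.56 and −1.54 on arrays 2, 3 and 4. The Ty3 rows YIL082W, YIL080W and YIL082W-A had means of 3.77, 2.21 and 1.78, of which the first was called and the last had −0.27 on array 4. In all, 28 partly measured genes of 2392 with a value in both dye orientations had a mean past 2-fold above 0 with 1 sign, and 4 below. Each mean covered 2 or 3 arrays, so 1 array could carry it. YLR379W had 3.87 on array 3 and 0.45 on array 4, and HXT12 0.56 and 3.49.

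The tests of the list difference and of mating type were chosen after the values were seen; the tests of the neighbours and of the adjacent pairs were set before their values were seen, but after the pair SNL1 and BAR1 was. The cell wall list lay further towards arrays 1 and 2 than the pheromone list, with medians of 0.12 and −0.15 for arrays 1+2 minus arrays 3+4, a difference of 0.265 (permutation of members between the lists, p = 0.029). The cell wall list had medians of 0.80, 0.81, 0.76 and 0.71 on arrays 1 to 4. The pairing is not known, genes are not independent and the difference was seen before it was tested, so it does not support a pairing.

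SNL1, which fell, lies beside BAR1, which rose. Neighbours of the called higher genes in the annotation were not lower in general: 42 tested neighbours had a median log2 ratio of 0.0634, against −0.0517 for neighbours of 1000 random gene sets (two-sided permutation p = 0.008, in the opposite direction to the prediction). The called higher rows YFL-TYB, YIL082W and YMR173W-A were not in the annotation and did not enter. Adjacent pairs of called genes, overlapping pairs left out, numbered 2 (AFB1/NFG1 and BAR1/SNL1), against a mean of 0.562 in random sets (one-sided permutation p = 0.11).

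Cells of the opposite mating type could bring mating pheromone into the cultures. Of the alpha-specific transcripts MF(ALPHA)1 and STE3, 0 arrays gave a value, so a mixed culture cannot be told apart from a response of the cells. MF(ALPHA)2 had 0.28, −0.68 and 0.65 on arrays 2, 3 and 4, and SAG1, also alpha-specific, 1.06, 1.477 and 1.96 on arrays 1, 3 and 4. Each culture was divided, so such cells would have been in both parts. The labels do not give the strain's mating type.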
